A study of Mus musculus with 6 samples.

How the data were processed

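The series holds 6 RNA-seq libraries of mouse Th17 cultures, 3 WT (floxed alleles, no Cre) and 3 PDH knockout (floxed alleles with CD4 Cre), grouped by the sample labels. Per the labels' protocols, naive CD4+ T cells were cultured for 3 days on plates coated with anti-CD3 (5 µg/mL), with antibodies to CD28 (1 µg/mL) and interferon γ (5 µg/mL) and the cytokines TGFβ (2 ng/mL) and IL-6 (30 ng/mL), RNA was isolated with a NucleoSpin kit, and libraries were made with a stranded mRNA kit. Cre is present in every knockout library and in no WT library, so the effect of Cre itself was not separated from that of the deletion.

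The deposited values are expected counts, estimated read counts per gene in whole numbers, with different totals per library. The submitters' processing notes name Salmon, DESeq2 and DESeq without versions or roles. The genome build and annotation release are not given in the sources used here, so no coordinates are printed. Each of the 15452 deposited rows holds at least 10 counts in at least 3 libraries, so low genes had been removed beforehand. The deposited counts were used as they stand, and no rounding was needed. Gene symbols were matched on the unversioned gene ID to GENCODE M21: 15138 IDs matched and 314 did not, and only 18 IDs carried the same version as that release, so the release used upstream was a different one. Where several IDs share a symbol, the ID with the highest mean count kept it and 13 others are given by ID. Reads of pseudogenes and paralogs can be split between entries by transcript quantification.

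Total counts ran from 33.80 M to 40.41 M (M, 1e6) per library. A count of 0 in a library allows up to 3 counts, about 0.08 CPM, and such floors and intervals cover counting error only. No replicates were alike enough to be a single library deposited again: the chi-square per degree of freedom between replicates was at least 25.17. The biological coefficient of variation was 13.8%.

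Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. filterByExpr removed 91 genes and left 15361. TMM scaling and a robust quasi-likelihood fit with genotype as the only term were followed by the quasi-likelihood F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM are TMM-scaled, except those summed over cell type markers, which use library totals. The 29 gene lists were fixed before the data were examined. The 27 lists with at least 5 tested members were tested by camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjusted over the 27. Camera calls 10 of them, 4 higher and 6 lower, and none with a correlation estimated from the data, while fry, which asks whether a set's genes move on balance one way, calls 15. For each list the number of members called was also counted adjusted over the list alone. Idh1 is in 2 lists. Summed markers and the mitochondrial share were compared by exact two-sided permutation over the 20 assignments of libraries to groups, whose smallest p is 0.1.

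Genes are named by a rule fixed before the data were examined: the 10 largest increases and 10 largest decreases among called genes with a mean of at least 50 normalized counts and no overlap between groups, leaving out predicted genes, receptor segments, sex-linked genes and unnamed IDs (1 increase was passed over), up to 4 called members of each list with the smallest p, or up to 2 where none was called, and a fixed set (Pdha1, Pdhb, Dlat, Il17a, Il17f, Il22, Foxp3, Acly, Slc2a1, Hk2, Cpt1a). Some genes that the rule takes are not reported here. Egln1, Egln2 and the genes of the closing observations were chosen after their values were seen.

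The test was tried on simulated counts for 15059 genes with 200 changed genes, 50 per fold size, and the TCA cycle list shifted as well. It called 12% of those changed 1.25-fold in the right direction, 30% at 1.5-fold, 54% at 2-fold and 86% at 4-fold. Of its calls, 8.7% were unchanged genes. In the data 47.59% of tested genes were called, a far larger share than was changed in the simulation. The adjustment is stricter where few genes change, so these rates do not carry over to the real test. Alternatives were other scalings (RLE, upper-quartile, library totals), DESeq2 1.42.0, limma-voom, no filter and a stricter filter (at least 50 counts in 3 libraries), no robust dispersion, a fold of at least 2, a test against 1.2-fold, the replicate number as a block, each library left out, and sex-linked genes and receptor segments left out. After the data were seen, 3 more were added: the summed B cell markers other than Cd74 as a covariate, leaving out the 3 libraries with raised B cell marker counts, and leaving out the entries over 5 times higher in knockout replicate 2 than in the other knockout libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.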

Results

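Messenger RNA was sequenced from mouse Th17 cells, the CD4+ helper T cells that make interleukin 17. Naive CD4+ T cells were sorted on magnetic beads from spleen and lymph node and cultured for 3 days under Th17 conditions, which combined T cell receptor and CD28 stimulation with IL-6, TGFβ and an antibody that blocks interferon γ. One group of 3 libraries came from mice with floxed alleles and no Cre and is called WT here. The other group of 3 came from mice that also carried CD4 Cre and is labelled as a knockout of PDH, pyruvate dehydrogenase, the mitochondrial complex that turns pyruvate into acetyl-CoA. The table held 15452 genes. Total counts were 37.56 M, 39.42 M and 40.41 M (M, 1e6) in WT replicates 1 to 3 and 39.40 M, 35.75 M and 33.80 M in knockout replicates 1 to 3. The single comparison asks how the transcriptome of Th17 cells differs when PDH is deleted in T cells. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples. Levels are given as CPM (counts per 1e6 counts, mean ± SD, n = 3 per group), changes as log2 fold change of knockout over WT ± SE, and adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. In every called gene named here except Il24, the 3 knockout values lay outside the range of the 3 WT values.

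The genes of the PDH complex were read first as a check of the labels. Pdha1 (ENSMUSG00000031299.11), which encodes the E1 alpha subunit, was at 248 ± 10.2 CPM in WT and 193 ± 6.33 CPM in knockout. Its values were 255.76, 236.09 and 250.85 CPM in the WT libraries and 198.43, 193.37 and 185.85 CPM in the knockout libraries, a log2 fold change of -0.36 ± 0.06 (adjusted p = 0.000871). Tested against a fold change of 1.2 rather than 0, it no longer passed (adjusted p = 0.0622). Dlat, the E2 subunit gene, fell from 81.8 ± 3.22 to 51.0 ± 1.06 CPM (-0.68 ± 0.06, adjusted p = 3.55e-05). Pdhb, the E1 beta subunit gene, was at 87.8 ± 3.52 and 79.5 ± 2.22 CPM (-0.14 ± 0.06, adjusted p = 0.063), and passed only when WT replicate 3 was left out (adjusted p = 0.0369). The labels do not name the floxed gene, and counts over a whole gene cannot show the loss of a single exon, so these values neither establish nor exclude the deletion. Sample titles spell the floxed locus PHD while the genotype labels spell it PDH. For that reason the prolyl hydroxylase genes, also abbreviated PHD, were read after the data were seen: Egln1 was at 93.8 ± 14.3 and 82.0 ± 5.56 CPM (adjusted p = 0.157), and Egln2 and Egln3 fell by 0.39 and 0.80 on the log2 scale (adjusted p = 0.00289 and 4.14e-05). Egln3 is also in the hypoxia list, where 8 of 15 tested genes fell and 0 rose, so its decrease does not single it out. These counts over whole genes do not show which gene was floxed either. Among 14 tested genes of the PDH complex and pyruvate entry, 2 rose, 6 fell and 6 were not called. Adjusted over the list alone, 2 rose and 7 fell. The kinase genes Pdk3 and Pdk1 fell (-0.47 ± 0.06 and -0.45 ± 0.07), and the phosphatase gene Pdp2 rose (0.50 ± 0.06). As a set the list did not pass (camera, adjusted p = 0.0907).

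Across the transcriptome, 7311 of 15361 tested genes differed between knockout and WT, 3548 higher and 3763 lower. Of the changed genes 48.53% were higher, and under upper-quartile scaling this share was 59.95%. A change of at least 2-fold was seen in 1627 genes, 1188 higher and 439 lower. Tested against a fold change of 1.2, 3981 genes passed. Groups did not overlap in 8941 genes, 58.21% of those tested, where chance gives 10%. The first principal component held 58.4% of the variance and separated the groups. Knockout replicate 2 differed from the rest in that 4.948% of its counts (Wilson 95% interval 4.941 to 4.955%, counting error only) fell on a single unnamed entry, ENSMUSG00000119584.1, against 0.080 to 0.215% in the other 5 libraries. Further entries were raised there, among them Lars2 at 6598 CPM and mt-Rnr1 at 1252 CPM (by library totals). Knockout replicates 1 and 3 held 834 and 780 CPM of Lars2 and 237 and 214 CPM of mt-Rnr1. The chi-square per degree of freedom of knockout replicate 2 against these libraries was 156.29 and 145.79, against 30.59 between them.

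The steepest increases among genes with a mean of at least 50 normalized counts began with a pair of entries at 0 in all WT libraries. Rpl15-ps3, a ribosomal protein pseudogene, was at 13.1 ± 0.185 CPM in knockout and at least 164-fold higher than a floor of 3 counts per library. The entry ENSMUSG00000116207.2, a second entry for Nnt, was at 17.97, 3.21 and 12.64 CPM in the knockout libraries and at least 141-fold higher (adjusted p = 0.0414). That call was lost when any 1 library other than knockout replicate 2 was left out (adjusted p from 0.0695 to 0.156), and with library totals as the scaling (adjusted p = 0.0516). The second Nnt entry shares sequence with the main one, so how counts divide between them is uncertain. Fscn1, an actin-bundling protein, followed at 0.464 ± 0.246 CPM in WT and 19.6 ± 4.48 CPM in knockout (5.39 ± 0.36, adjusted p = 6.97e-05). Aqp4, a water channel, rose by 4.88 ± 0.17 (adjusted p = 9.28e-07), and Krt16, Fer1l6, Dagla, Aoc1, Ifit1 and Vcam1 rose by 4.87, 4.36, 4.06, 3.66, 3.65 and 3.64. Among the decreases, Ramp3, a receptor activity-modifying protein, went from 6.69 ± 3.15 to 0.331 ± 0.119 CPM (-4.34 ± 0.49, adjusted p = 0.000474), and Tg, thyroglobulin, from 45.2 ± 9.78 CPM to a mean of 3.88 CPM, with values from 2.62 to 5.01 (-3.55 ± 0.29, adjusted p = 0.000305). Metrnl, Ccn1, Plaur, Matk, Il12rb2, Spock2, Crem and Tgm2 followed, with log2 fold changes from -3.38 to -2.55. Il12rb2, a subunit of the IL-12 receptor, fell from 123 ± 38.3 to 20.2 ± 2.19 CPM, and Crem, a cAMP-responsive transcription factor, from 123 ± 19.9 to 20.8 ± 0.707 CPM.

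The Th17 genes split in direction. The signature cytokine gene Il17a fell from 154 ± 6.41 to 62.2 ± 6.71 CPM (-1.31 ± 0.08, adjusted p = 1.02e-05) and Il17f from 664 ± 114 to 290 ± 61.9 CPM (-1.19 ± 0.19, adjusted p = 0.00341). Il23r, the receptor subunit through which IL-23 maintains Th17 cells, fell from 20.3 ± 1.76 to 4.16 ± 1.16 CPM (-2.28 ± 0.18, adjusted p = 3.55e-05). Il22 was at 1.03 ± 0.286 and 0.586 ± 0.225 CPM (-0.81 ± 0.34, adjusted p = 0.0758), and passed when WT replicate 2 or knockout replicate 1 was left out (adjusted p = 0.0308 and 0.0328). In the other direction, Tmem176a rose from 25.1 ± 4.74 to 77.0 ± 4.32 CPM (1.61 ± 0.12) and Ccr6, the chemokine receptor of Th17 cells, from 39.9 ± 3.17 to 70.9 ± 7.94 CPM (0.83 ± 0.09). Of 22 Th17 genes tested, 8 rose, 8 fell and 6 were not called. Adjusted over the list alone, 9 rose and 9 fell. As a set the list was not called (camera, adjusted p = 0.931), its camera direction being up while its median and mean log2 fold changes were -0.06 and -0.02.

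**Figure D1:**
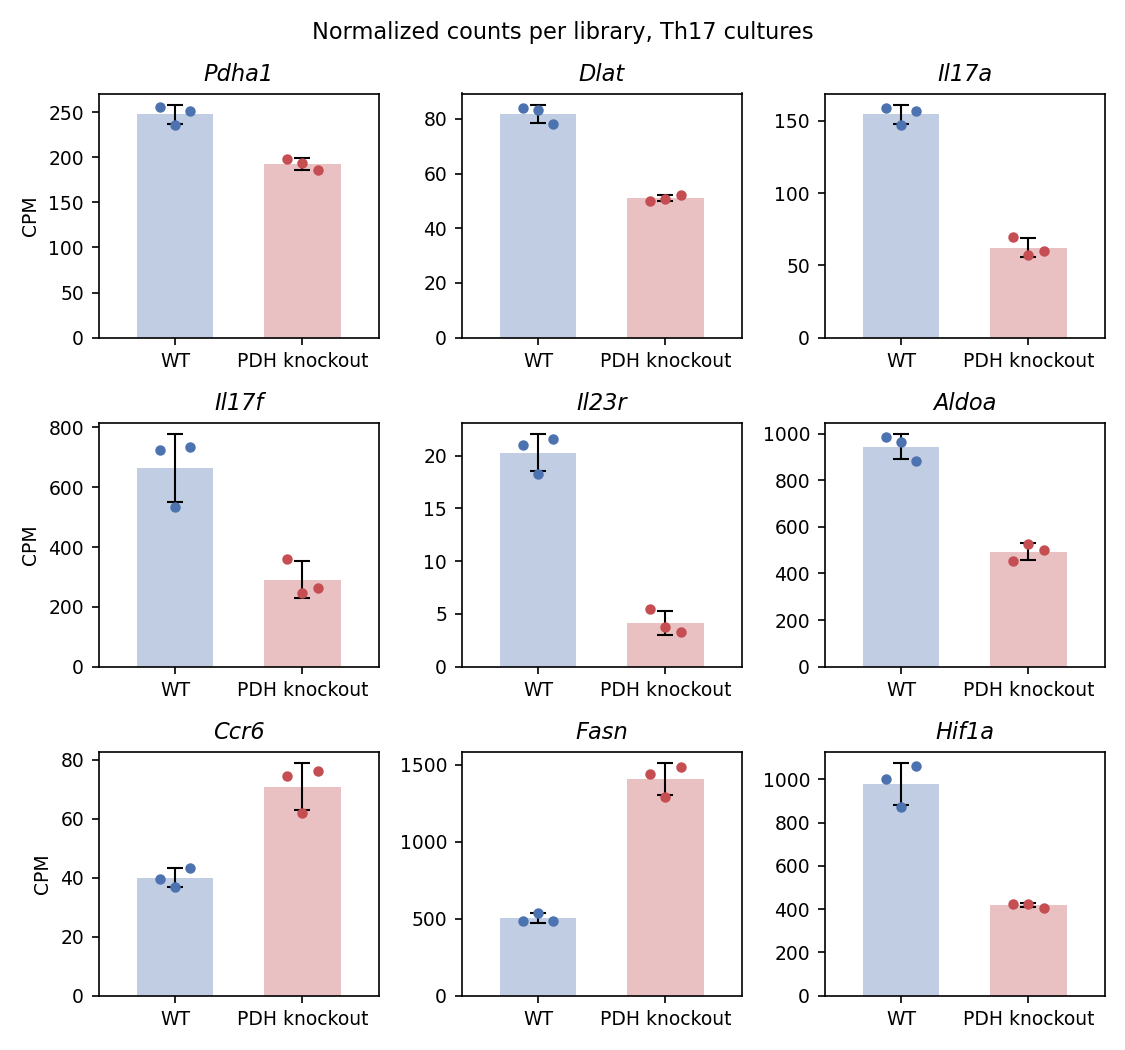
CPM (y axis, linear, from 0) of 9 genes in the 3 WT and 3 PDH knockout libraries; bars are means, error bars SD and points single libraries. Il17a, Il17f, Il23r, Aldoa and Hif1a lay lower and Ccr6 and Fasn higher in all 3 knockout libraries.

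Genes of the other helper T cell programmes moved in both directions, and none of these lists passed as a set. Of 14 Th1 genes, 3 rose and 6 fell (camera, adjusted p = 0.321). Stat4, a transducer of IL-12 signals, fell from 115 ± 12.3 to 36.8 ± 7.31 CPM (-1.65 ± 0.16) and Fasl by 1.95 on the log2 scale, while Il18rap, a subunit of the IL-18 receptor, rose from 7.64 ± 0.782 to 22.9 ± 4.52 CPM (1.58 ± 0.15) and Ccl5 rose by 2.26. Of 7 Th2 genes, 1 rose and 3 fell (camera, adjusted p = 0.382), with Ccr8 at -0.79 ± 0.09, Il4ra at -0.38 ± 0.07 and Il1rl1 at 1.93 ± 0.34. Il24 fell (adjusted p = 0.0315) with overlapping groups, and its call was lost when any single library except WT replicate 2 was left out (adjusted p from 0.0519 to 0.0983) and by limma-voom (adjusted p = 0.108). Of 14 regulatory T cell genes, 3 rose and 6 fell (camera, adjusted p = 0.177). Ctla4, an inhibitory receptor, fell from 630 ± 38.1 to 236 ± 22.1 CPM (-1.42 ± 0.08, adjusted p = 7.83e-06), Tigit fell by 1.69 and Gpr83 by 0.90, and the integrin gene Itgae rose by 1.88. Foxp3, the defining regulatory T cell transcription factor, was at 18.0 ± 2.78 and 12.9 ± 4.35 CPM (-0.48 ± 0.24, adjusted p = 0.146). It passed when knockout replicate 2 was left out (-0.79, adjusted p = 0.00323) and by DESeq2 (adjusted p = 0.0472). WT replicate 2 and knockout replicates 2 and 3 held raised B cell marker counts. Without them, which leaves knockout replicate 1 alone in its group, Foxp3 was at -0.90. Among 12 naive and memory T cell genes, 5 rose and 2 fell (camera, adjusted p = 0.311), with Bach2 at 0.48 and Foxp1 at 0.34 against Satb1 at -0.43. Adjusted over the list alone, 3 and 6 Th1, 1 and 3 Th2, 4 and 7 regulatory and 6 and 2 naive and memory genes rose and fell.

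Of 22 T cell activation genes, 3 rose, 8 fell and 11 were not called, and the counts adjusted over the list alone were also 3 and 8. Nr4a2, an immediate-early nuclear receptor, fell from 36.7 ± 1.61 to 10.0 ± 1.55 CPM (-1.87 ± 0.11, adjusted p = 1.01e-05). The costimulatory receptor genes Tnfrsf9 and Tnfrsf4 fell by 1.76 and 0.90 on the log2 scale. Myc, a driver of growth in activated T cells, rose from 288 ± 23.6 to 512 ± 34.4 CPM (0.83 ± 0.08, adjusted p = 5.47e-05). As a set the list was not called (camera, adjusted p = 0.352).

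Of 69 nuclear-encoded respiratory chain genes, none rose, 60 fell and 9 were not called, with a median log2 fold change of -0.43. Uqcrfs1, the Rieske subunit of complex III, fell from 139 ± 3.62 to 72.6 ± 7.34 CPM (-0.94 ± 0.08, adjusted p = 2.72e-05), Atp5d by 0.80, Atp5h by 0.63 and Cox4i1 by 0.63. Of 20 TCA cycle genes 0 rose, 16 fell and 4 were not called, the decreases including Suclg1 (-0.74 ± 0.07), Idh2 (-0.64 ± 0.08) and Mdh1 (-0.48 ± 0.06). Of 22 glycolysis genes 2 rose, 17 fell and 3 were not called. Aldoa, aldolase A, fell from 944 ± 53.5 to 493 ± 36.0 CPM (-0.94 ± 0.08), Pfkm, Pfkp and Hk1 by 0.91, 0.79 and 0.70, and Hk2 by 0.56. Slc2a1, the glucose transporter GLUT1, was at 85.4 ± 16.4 and 70.6 ± 2.79 CPM (adjusted p = 0.107), and passed when WT replicate 3 was left out (adjusted p = 0.00734) and with the replicate number as a block (adjusted p = 0.0422). Adjusted over the list alone, 64 respiratory chain and 17 TCA cycle genes fell, and in glycolysis 2 rose and 17 fell. By camera with a preset correlation of 0.01, adjusted p was 6.36e-14 for the respiratory chain, 6.5e-06 for the TCA cycle and 3.28e-05 for glycolysis. None of these calls held with an estimated correlation (adjusted p = 0.435, 0.229 and 0.421 with an estimated correlation).

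Of 23 genes of fatty acid uptake and oxidation 0 rose, 14 fell and 9 were not called. Acads, short-chain acyl-CoA dehydrogenase, fell from 42.3 ± 2.54 to 22.3 ± 0.827 CPM (-0.93 ± 0.07, adjusted p = 2.56e-05), Etfb, an electron transfer flavoprotein, by 0.87, Acsl4 by 0.70 and Acadvl by 0.54. Cpt1a, which admits long-chain fatty acids to mitochondria, fell from 54.5 ± 3.10 to 35.6 ± 3.10 CPM (-0.62 ± 0.08). Of 15 hypoxia genes outside glycolysis 0 rose, 8 fell and 7 were not called. Hif1a, the hypoxia-inducible transcription factor, fell from 979 ± 96.8 to 418 ± 9.83 CPM (-1.23 ± 0.08, adjusted p = 1.42e-05), and Bnip3 and Higd1a by 1.41 and 0.60. Adjusted over the list alone, 14 and 9 genes fell. Camera gave adjusted p = 0.000114 and 0.00382 for the lists, and adjusted p = 0.229 for both with an estimated correlation. The 13 mitochondrially encoded respiratory chain genes did not follow: 1 rose, 1 fell, neither was called when adjusted over the list alone, and the set was not called (camera, adjusted p = 0.801). The called genes were mt-Nd5 (0.23 ± 0.08) and mt-Nd1 (-0.27 ± 0.09), and leaving out 1 library ended the mt-Nd5 call in 5 of 6 cases (adjusted p from 0.051 to 0.146) and the mt-Nd1 call in 5 of 6 (adjusted p from 0.0633 to 0.108).

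**Figure D2:**
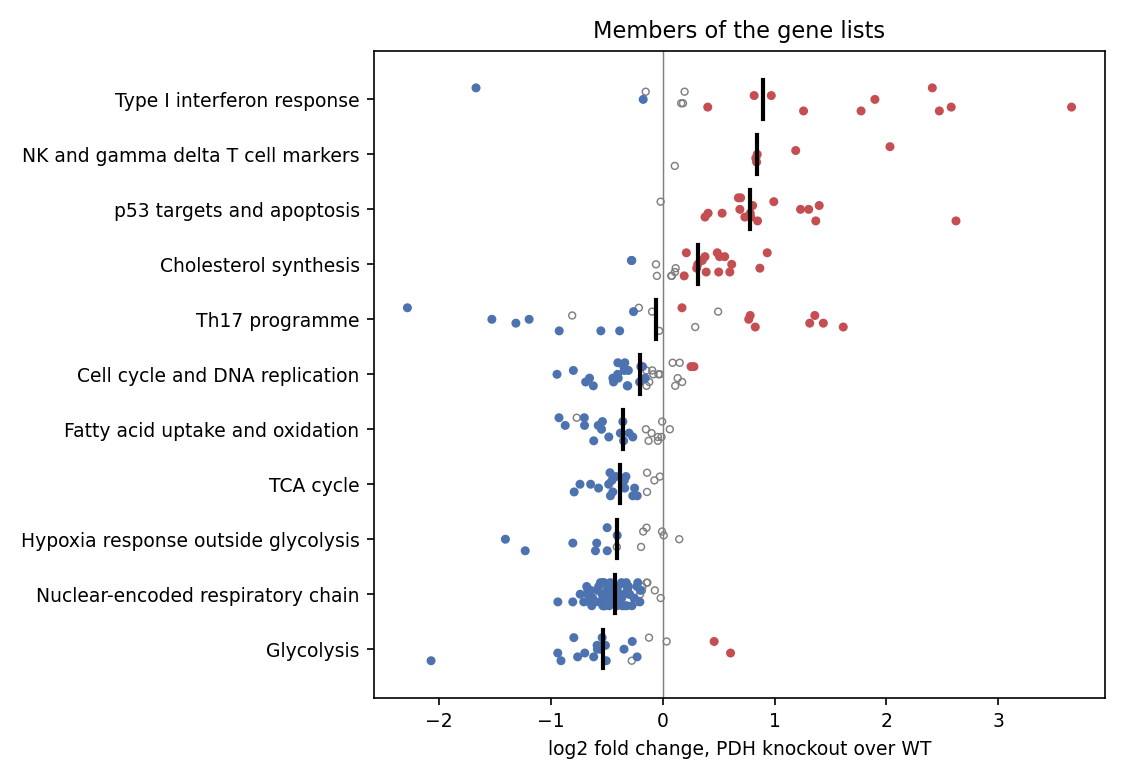
Log2 fold change (x axis, PDH knockout over WT) of each tested member of the 10 gene lists called by camera and of the Th17 list; filled points passed adjusted p of 0.05 (red higher, blue lower), open points did not, and the black bar is the median. Members of the respiratory chain list lay to the left of 0, and 17 of 18 p53 target and apoptosis genes to the right.

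Genes of lipid synthesis did not move as one. Fasn, fatty acid synthase, rose from 503 ± 31.7 to 1406 ± 104 CPM (1.48 ± 0.08, adjusted p = 6.22e-06) and Acaca, acetyl-CoA carboxylase, from 188 ± 1.62 to 315 ± 19.6 CPM (0.75 ± 0.06). The elongase gene Elovl6 fell from 70.4 ± 1.24 to 38.1 ± 2.51 CPM (-0.89 ± 0.07) and Acss1, mitochondrial acetyl-CoA synthetase, by 1.17. Acly, ATP citrate lyase, which makes cytosolic acetyl-CoA from exported citrate, was at 649 ± 23.6 and 700 ± 4.56 CPM (0.11 ± 0.06, adjusted p = 0.163). Acly passed with upper-quartile factors (adjusted p = 0.0281) and with a filter of at least 50 counts (adjusted p = 0.0498). Of the 17 genes of citrate export, acetyl-CoA and fatty acid synthesis, 4 rose and 5 fell, also when adjusted over the list alone (camera, adjusted p = 0.801). In cholesterol synthesis 15 of 23 genes rose and 2 fell, with the same counts adjusted over the list alone. Idi1 rose from 377 ± 28.3 to 720 ± 24.3 CPM (0.93 ± 0.07, adjusted p = 2.18e-05), and Lss and Acat2 by 0.62 and 0.50. Camera called the list higher (adjusted p = 0.00142, and adjusted p = 0.421 with an estimated correlation).

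Amino acid genes were mixed as well. Of 18 genes of glutamine and amino acid supply 5 rose and 6 fell, also when adjusted over the list alone (camera, adjusted p = 0.801, direction down and mean -0.05 where the median was 0.06). The transaminase genes Got1, Got2 and Bcat2 fell by 0.81, 0.54 and 0.48, and Gls2, a glutaminase, from 17.3 ± 0.569 to 8.20 ± 0.998 CPM (-1.07 ± 0.11). In serine and one-carbon metabolism 1 of 13 genes rose and 2 fell, Psph (-0.90 ± 0.13) and Gcsh (-0.47 ± 0.10), with the same counts adjusted over the list alone (camera, adjusted p = 0.54). An alternative chosen after the data were seen left out the 3 libraries that held raised B cell marker counts (WT replicate 2 and knockout replicates 2 and 3). It leaves knockout replicate 1 alone in its group, and there Gcsh was at -0.30 and not called. Of 20 ATF4 and integrated stress response genes 5 rose and 3 fell, again also adjusted over the list alone. Sesn2 rose from 38.6 ± 4.94 to 93.1 ± 5.32 CPM (1.27 ± 0.09) and Atf5 by 1.24, while Atf3 and Sars fell by 1.67 and 0.51. The set was not called (camera, adjusted p = 0.382), and passed as higher when knockout replicate 2 was left out (adjusted p = 0.0342). Its pass without the 3 libraries that held raised B cell marker counts rests on knockout replicate 1 alone, so it holds no spread between knockout libraries.

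Of 18 genes listed as p53 targets and apoptosis regulators, 17 rose and none fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.78. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose from 16.6 ± 0.691 to 41.1 ± 3.06 CPM (1.31 ± 0.08, adjusted p = 1.02e-05), Bbc3, which encodes PUMA, from 13.4 ± 1.57 to 31.5 ± 4.55 CPM (1.23 ± 0.12), and Eda2r by 2.62. Bcl2l1, which opposes apoptosis, rose by 0.80. Of 34 cell cycle and DNA replication genes 2 rose and 20 fell, also when adjusted over the list alone. Ccnb2, a mitotic cyclin, fell from 98.3 ± 4.33 to 51.1 ± 2.64 CPM (-0.94 ± 0.06, adjusted p = 1.61e-05), and Tk1, Plk1 and Ccne1 by 0.80, 0.69 and 0.62. Camera gave adjusted p = 3.17e-06 for the p53 and apoptosis list and 0.00142 for the cell cycle, and adjusted p = 0.435 and 0.59 with an estimated correlation. Without the 3 libraries that held raised B cell marker counts, which leaves knockout replicate 1 alone in its group, the cell cycle set was not called.

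Of 16 interferon-stimulated genes tested, 10 rose and 2 fell, also when adjusted over the list alone. Ifit1 rose from 0.287 ± 0.141 to 3.64 ± 1.08 CPM and Mx1 from 0.362 ± 0.128 to 2.18 ± 0.147 CPM (2.58 ± 0.28), while Ifitm3 fell by 1.67. The set was called higher (camera, adjusted p = 0.00888, and adjusted p = 0.315 with an estimated correlation). Of 27 genes of histone acetyl transfer and removal, 7 rose and 6 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.931). The deacetylase gene Sirt1 rose by 0.76 and Sirt2 fell by 0.63, the acetyltransferase gene Crebbp rose by 0.68 and the acetyl-histone reader gene Brd2 by 0.67. Of 19 NRF2, redox and pentose phosphate genes 2 rose and 8 fell, also adjusted over the list alone, with Gpx4, which protects lipids from peroxidation, at -0.80 ± 0.06, Taldo1 at -0.75 ± 0.06, Srxn1 at -1.01 ± 0.17 and Sod2 at -0.38 ± 0.06. That set had adjusted p = 0.0561 and passed when WT replicate 3 or knockout replicate 1 was left out (adjusted p = 0.0234 and 0.0202).

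Markers of other cell types differed between libraries. Summed over 13 B cell markers, WT libraries held 111.5, 211.1 and 98.08 CPM and knockout libraries 238.1, 347.2 and 546.9 CPM (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The difference was 237.1 CPM, and 152.4 CPM without knockout replicate 3. Cd74, the class II invariant chain, was the 1 called marker and was higher in all 3 knockout libraries (2.00 ± 0.29, adjusted p = 0.00461), knockout replicate 1 included. With Cd74 set aside, the sums were 73.28, 151.6 and 60.73 CPM in WT and 71.19, 196.5 and 302.3 CPM in knockout, and on this ground WT replicate 2 and knockout replicates 2 and 3 are called raised here. The list was not called (camera, adjusted p = 0.106), and passed without WT replicate 2 or without knockout replicate 1 (adjusted p = 0.0213 and 0.00141). Of 6 NK and γδ T cell markers 5 rose, all from about 2 CPM or less, including Trdc from 2.02 ± 0.380 to 3.62 ± 0.413 CPM, Tcrg-C4 (1.19 ± 0.26) and Sox13 (2.03 ± 0.45). Their summed level was 5.68 ± 1.02 and 10.5 ± 1.66 CPM (exact permutation p = 0.1). This list was called (camera, adjusted p = 0.0368, and adjusted p = 0.435 with an estimated correlation), but not without WT replicate 3 (adjusted p = 0.071), with library totals as the scaling (adjusted p = 0.0505) or with the replicate number as a block (adjusted p = 0.0523). Without the 3 libraries that held raised B cell marker counts, which leaves 1 knockout library, Trdc, Tcrg-C4 and Sox13 were at 0.81, 0.71 and 1.355 and not called (adjusted p = 0.0591, 0.179 and 0.127), and Klrd1 of the next list was at -0.65 (adjusted p = 0.0583). Of 5 CD8 T cell markers 2 fell, Klrd1 (-1.01 ± 0.21) and Cd8b1 (-0.62 ± 0.16). The sum over the 5 was 31.1 ± 1.31 and 21.7 ± 8.32 CPM (exact permutation p = 0.2), and the list was not called (camera, adjusted p = 0.274). It passed without the 3 libraries with raised B cell marker counts, but there knockout replicate 1, which held the lowest sum (14.11 CPM), stands alone. The difference in the CD8 sum was -9.44 CPM, and -5.66 CPM without knockout replicate 1. Of 8 myeloid markers none was called, Adgre1 and Lyz2 coming closest (adjusted p = 0.0692 and 0.0808), and the sum over 9 markers in the table was 14.8 ± 7.91 and 8.74 ± 2.62 CPM (exact permutation p = 0.3; camera on the 8, adjusted p = 0.604). WT replicate 1 held 23.88 CPM of it, and without that library the difference went from -6.01 to -1.45 CPM. Adgre1 and Lyz2 passed by DESeq2 (adjusted p = 0.00346 and 0.0235) and by edgeR without robust dispersion (adjusted p = 0.0354 and 0.0236), Lyz2 with the replicate number as a block (adjusted p = 0.0284), and Adgre1 when knockout replicate 3 was left out (adjusted p = 0.0449). Car2, the single erythroid marker tested, rose from 1.30 ± 0.0377 to 2.71 ± 0.527 CPM (1.06 ± 0.21; exact permutation p = 0.1 for its summed level). Adjusted over each list alone, the counts for the B cell, NK and γδ, CD8, myeloid and erythroid lists were the same.

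**Figure D3:**
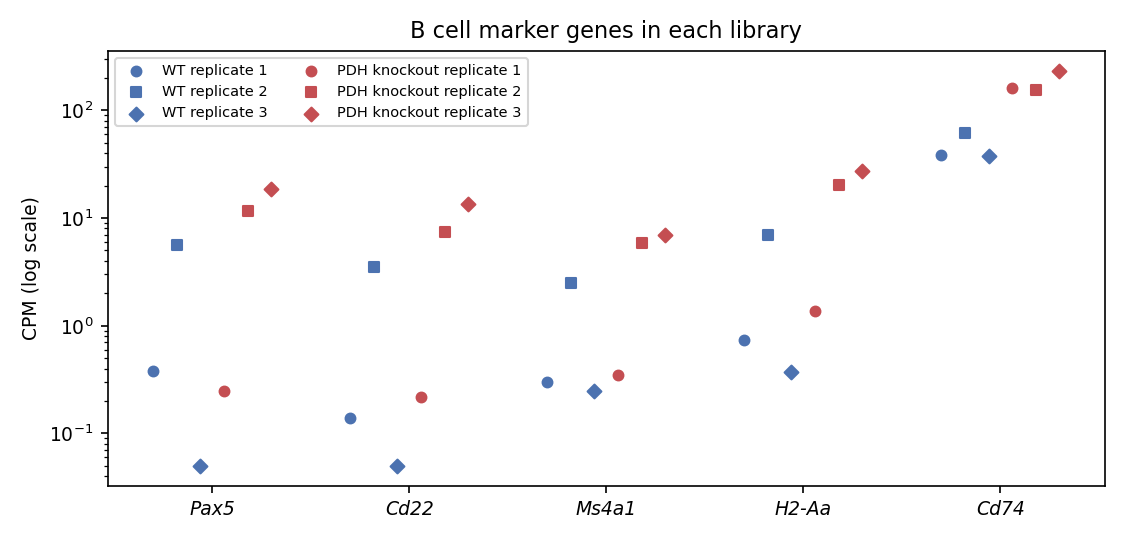
CPM (y axis, log scale) of 5 B cell marker genes in each library; colour gives the group and symbol shape the replicate number. Pax5, Cd22, Ms4a1 and H2-Aa were high in WT replicate 2 and knockout replicates 2 and 3, while Cd74 was higher in all 3 knockout libraries.

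Xist, the RNA of the inactive X chromosome, was abundant in all 6 libraries and higher in knockout, at 1554 ± 213 and 2616 ± 186 CPM (0.75 ± 0.10, adjusted p = 0.000379). Of the 6 sex-linked genes listed 3 were tested, and 2 of these rose, also adjusted over the list alone. The other was the Y-linked Kdm5d, at 7.15 ± 0.961 and 9.27 ± 0.555 CPM. Its call was lost when any single library except WT replicate 3 was left out (edgeR adjusted p from 0.0606 to 0.128). The labels do not give the sex of the mice, and it was not inferred from these values. Mitochondrially encoded genes took 3.26 ± 0.319% of counts in WT and 3.29 ± 0.399% in knockout (exact permutation p = 1).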

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

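Leaving out the 3 libraries with raised B cell marker counts, and leaving out the entries high in knockout replicate 2, were chosen after the data were seen, as was the B cell covariate; the other alternatives were fixed before. Against 7311 changed genes (3548 higher, 3763 lower), the test against 1.2-fold gave 3981 (2125 and 1856) and a fold of at least 2 gave 1627 (1188 and 439), both stricter by construction. All other settings gave 5308 to 7313 genes. Leaving out 1 library gave 5524 to 6961 (2604 to 3333 higher, 2920 to 3643 lower), and leaving out the B cell libraries gave 5308, where the lone knockout library is assumed to vary like the WT ones. Genes called in both the main and an alternative setting kept their direction in every setting compared, which leaves out the B cell covariate. Upper-quartile factors moved the share of higher genes from 48.53 to 59.95%. Neither the fold of at least 2 nor the B cell covariate was read for single named genes. In all other settings Pdha1 stayed lower, from -0.40 to -0.28 (adjusted p from 7.7e-08 to 0.0622). Among these it lost its call only in the test against 1.2-fold (-0.36). Its change of 1.286-fold also falls short of a fold of at least 2. Of the 124 named genes, Pdha1 aside, 103 kept call and direction in every setting that gave a value and 20 did not.

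Camera called 10 lists, 0 with an estimated correlation, 15 by fry, and 10 to 12 with 1 library left out. The cause of these differences was not tested. A larger correlation does not account for every loss. The hypoxia list, with an estimated correlation of -0.008 against the preset 0.01, went from 0.00382 to 0.229 (camera, adjusted p). Estimates were 0.017, 0.029 and 0.036 for the interferon, fatty acid oxidation and TCA cycle lists, and 0.578 for the p53 and apoptosis list. Fry kept all 10 lists, but unlike camera it does not compare a list with the other genes. As 47.59% of tested genes were called, its calls are no check of the camera calls. The direction of the 10 called lists held in the 13 alternatives run for lists; the other settings were run for genes alone. The lists that fry adds were PDH, Th2, Treg, naive and memory, and NRF2 (0.00154, 0.0133, 0.0027, 0.0303 and 0.0279). Lists that were never called turned direction, with adjusted p as follows: fatty acid synthesis by fry (0.942); histone acetylation by fry (0.944), without WT replicate 3 (0.944), knockout replicate 3 (0.883) or the B cell libraries (0.881); Th17 with library totals (0.944), without knockout replicate 1 (0.88) or the B cell libraries (0.91); mitochondrially encoded genes without WT replicate 2 (0.954) or knockout replicate 1 (0.976); glutamine supply without knockout replicate 2 (0.974) or the B cell libraries (0.63). With 1 library left out, adjusted p ran from 0.773 (without WT replicate 3) to 0.984 (without knockout replicate 3) for the Th17 programme, from 0.551 (without WT replicate 3) to 0.974 for Glutamine and amino acid supply, from 0.366 to 0.976 for the Mitochondrially encoded respiratory chain, and from 0.868 to 0.989 (without WT replicate 2) for Histone acetyl transfer and removal. The cause was not tested.

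The replicate number as a block gave 7218 genes and 9 lists, the NK and γδ list being lost (0.0523) and histone acetylation turning (0.97). Correlations of same-numbered libraries were -0.098, 0.093 and -0.259, and only knockout replicate 2 correlated best with the WT library of its own number, so the numbers were not taken to pair the samples. Differences in summed markers with 1 library left out ran from 152 to 307 CPM (B cell), 3.98 to 5.64 (NK and γδ), -13.9 to -5.66 (CD8), -8.45 to -1.45 (myeloid) and 1.18 to 1.80 (erythroid), and in the mitochondrial share from -0.178 to 0.220 points.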

Other observations

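All tests in this part were chosen after the data were seen. The groups in these opening paragraphs were picked after the values were seen and were not tested for enrichment. Of 81 cytosolic ribosomal protein genes 0 rose, 48 fell and 33 were not called (median log2 fold change -0.24), of 78 mitochondrial ribosomal protein genes 3 rose, 43 fell and 32 were not called (-0.27), and of 39 proteasome subunit genes 1 rose, 28 fell and 10 were not called (-0.28). T cell receptor V segments fell in 55 of 95 cases, rose in 1 and were not called in 39, and their summed level was 285 ± 18.1 CPM in WT and 212 ± 10.4 CPM in knockout (SD, n = 3). Of 7 T cell receptor constant genes 4 rose and 1 fell (median 0.83): the 4 were γδ genes, Trac fell from 308 ± 20.2 to 179 ± 18.3 CPM, and Trbc1 and Trbc2 were at -0.07 and -0.02 (edgeR adjusted p = 0.542 and 0.876). Cd4 fell from 488 ± 3.33 to 345 ± 19.4 CPM, while Cd3e was at 137 ± 5.61 and 133 ± 5.55 CPM (edgeR adjusted p = 0.568).

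Fosl2 and Pde4d, noticed because they were low, fell by 2.13 and 1.59 on the log2 scale. Cyp1a1, a target of the aryl hydrocarbon receptor, rose from 2.02 ± 0.324 to 22.7 ± 2.78 CPM (3.49 ± 0.15, edgeR adjusted p = 1.5e-06). Of its other targets looked at, Cyp1b1 and Ahrr both rose by 0.88, and Tiparp was at -0.19 (edgeR adjusted p = 0.0893).

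The 111 genes of the respiratory chain, TCA cycle and glycolysis lists had a median log2 fold change of -0.44. With a trend on transcript length and GC content over all genes removed, the median was -0.38 (bootstrap 95% interval -0.42 to -0.31). Without knockout replicate 2 and its unnamed abundant entry it was -0.46 (-0.49 to -0.38). These medians argue against the trend and against that library as the whole cause. Bootstraps here and below resampled genes or entries as if independent, not libraries, so their intervals hold no spread between samples. The summed B cell markers other than Cd74 were then set as a covariate over all 6 libraries. With it the 111 genes had a median of -0.45 (-0.49 to -0.39), with 88 lower and 0 higher by edgeR. This argues against B cells as the whole cause. The median of the B cell markers other than Cd74 moved from 1.93 to -0.14, which follows largely from the covariate being their own sum. The deletion and Cre, which go together in every library, stay open as untested. A trend with expression level was not tested for these 111 genes and stays open too.

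Of 1777 noncoding and unconfirmed entries 583 rose and 77 fell, with a median log2 fold change of 0.50. Against protein-coding genes of the same mean CPM the excess was 0.13 (bootstrap 95% interval 0.10 to 0.17), so for all entries together a trend with expression level cannot be told apart from a change of the class, as the interval reaches the bound of 0.1 set for it. For the 155 entries of 5 to 20 CPM the excess was 0.50 (0.37 to 0.60), and their median of 0.47 (0.34 to 0.55) stood against the 0.03 that an additive background such as genomic DNA would predict, which argues against both for these entries. A larger share of nuclear RNA in the knockout libraries cannot be told apart from a change of the class: 4 of 4 textbook nuclear RNAs, Malat1, Neat1, Xist and Kcnq1ot1, were higher by edgeR, but they are themselves among the 1777 entries. Genotype stays open as a biological explanation, untested.

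The second Nnt entry and Rpl15-ps3 had counts in knockout libraries only. The main Nnt entry was at 25.96, 26.42 and 25.80 CPM in WT and 8.61, 23.51 and 13.71 CPM in knockout, and the sum of both entries was 26.1 ± 0.325 and 26.6 ± 0.185 CPM (SD, n = 3), a ratio of 1.02. This is consistent with reads moving between entries because of an allele or strain difference between the mouse groups, for Nnt. Reads shared with Rpl15 at the ratio seen in knockout would give 1890 Rpl15-ps3 counts over the WT libraries, and 0 were seen. This argues against sharing at the same ratio in both groups. Sharing in the knockout libraries alone, as with an allele that differs between the groups, would also leave 0 in WT and stays open. The Nnt split also varied within the knockout group. The second entry was at 17.97, 3.21 and 12.64 CPM, and replicate 2 lay nearest to WT in both entries. On the allele reading the knockout libraries would thus differ among themselves at Nnt. Rpl15-ps3 was even, at 13.19, 13.23 and 12.89 CPM. Where a genetic difference goes with genotype, part of the other changes could come from it, which was not tested.

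For the 7311 changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one, and the highest other split gave 0 genes by edgeR. For the 10 gene lists, 4 of the 10 splits gave as many, and the highest other split gave 13 lists. With 10 splits the share cannot fall under 0.05. Every other split also mixes the genotypes in both groups. A genotype effect then widens the spread within groups and remains in part between them. The 0 genes and 13 lists are thus no measure of false calls.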
